A study of Mus musculus with 9 samples.

How the data were processed

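The samples are explanted mouse sarcomas of C57BL/6 mice that were frozen until use. Per the labels' protocols, total RNA was purified on columns with DNase digestion, and biotin-labelled cRNA was made with a 3'-IVT kit, which primes from the poly(A) tail, so that signal comes from the 3' ends of transcripts. The deposited values are intensities on a linear scale, 1 column per tumour, and per the submitters' processing notes they were made with RMA, whose version is not given in the sources used here. RMA corrects background, equalizes the distribution of probe values between arrays and summarizes the probes of a probe set, which can hide a global shift in RNA content and compresses low signals. The values run from 8.45 to 31403, and their log2 was taken before any other step, because the tests need a log scale and the design foresaw either scale. All 9 columns were used. No pair of arrays shared more than 3.63% of identical values, so every array was counted as 1 sample.

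Probe sets were named through GEO's platform annotation. Of 45101 probe sets, 64 controls were left out, 34945 carried 1 gene symbol, 932 several and 9160 none. Only those with 1 symbol were used for genes, and 99.4% of their gene IDs were found in a RefSeq gene table of mouse assembly GRCm38.p6, where no symbol differed. Each of the 18193 genes was represented by its probe set with the highest mean over the 9 arrays, with no filter on low values. Pten, Trp53 and the Y-linked gene Ddx3y were not analysed here because no probe set used carries their symbols, so the planned results on Pten and Trp53 levels were not run.

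Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend) between the 4 Pten-het and 5 Pten-WT arrays, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Differences are Pten-het minus Pten-WT on the log2 scale with their SE, and SDs are between tumours. The 38 gene lists, holding 633 members of which 577 were measured, were tested with camera at its preset inter-gene correlation of 0.01, adjusted over the lists. They cover Notch genes, PI3K, FOXO and p53 outputs, growth and stress programmes, the stroma, and the cell types a sarcoma sample can hold. A list score is the mean over the list's genes of each gene's log2 value minus its mean over the 9 arrays. The Notch target list was also tested with an exact permutation of its mean over all splits of the arrays into 4 and 5, and likeness of arrays with a one-sided exact permutation of correlations.

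The genes, lists, tests and most alternatives were fixed before the data were examined. Named genes are the 12 higher and 12 lower genes with an absolute log2 difference of at least 1 and the smallest unadjusted p (since none passed), every measured Notch receptor, ligand and target, and up to 4 members of each other list with the smallest unadjusted p, from which examples are given. Other genes, such as those described for single tumours, were chosen after their values were seen. Alternatives were each array left out, quantile normalization, median centring, array weights, other variance priors, a filter on low values, other choices of probe set, looser thresholds, other set tests and the replicate number as a block. Leaving out arrays in pairs and the Y-linked signal (present or absent) as a covariate were added after seeing the data. Only Pten-WT arrays carry that signal, so the covariate leaves Pten-WT replicate 4 as the sole comparator.

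The limma step was tested on simulated data made with the means and variances of these arrays, with 200 of 18193 genes changed in each of 10 rounds. In this comparison of 4 with 5 arrays it recovered 33.8% of log2 changes of 1, 68% of changes of 2, 86.4% of changes of 3 and 94.6% of changes of 4, with 6.1% false calls. The simulated genes varied independently and with the same spread in both groups. In the real arrays the median SD was 0.50 in Pten-het and 0.29 in Pten-WT tumours, so these shares may overstate what could be found. Figures were drawn with matplotlib 3.10.9. The arrays have no read depth, and low probe sets near the floor of the scale understate differences.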

Results

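Transcript levels were measured in 9 mouse tumours classed as high-grade undifferentiated pleomorphic sarcoma, a soft tissue cancer whose cells show no clear line of differentiation. Of these, 4 tumours were heterozygous for both Pten and p53 (called Pten-het here) and 5 were wild type for Pten and heterozygous for p53 (called Pten-WT). Pten is the lipid phosphatase that opposes PI3K, and p53, encoded by Trp53, is a tumour suppressor transcription factor. The design compares the genotypes, and the title of the series names Notch signalling. The question is therefore which transcripts, and in particular which Notch genes, differ between the genotypes. Y-linked signal was present in 4 of the 5 Pten-WT and 0 of the 4 Pten-het tumours. Any difference between the genotypes may thus also reflect the sex of the animals, which no label gives. Each tumour gave 1 array of 45101 probe sets, and the median intensity per array lay between 49.2 and 52.3. The labels do not say that the tumours came from separate animals, so p-values measure the spread between these samples. The number of arrays limits the precision of every difference. Pten and Trp53 themselves were not analysed here because no probe set used here carries either symbol, so the genotype labels were not checked against the arrays.

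Among the named genes with a lower level in the Pten-het tumours were Rpl39l, a paralog of the ribosomal protein gene Rpl39, the PDGF receptor-like gene Pdgfrl, and Pmepa1, a TGF-beta target that restrains SMAD signalling. Rpl39l had a log2 intensity of 7.03 ± 1.54 (SD, n = 4) in Pten-het and 12.55 ± 2.04 (SD, n = 5) in Pten-WT tumours, a difference of -5.52 ± 1.06 (SE). The difference was -2.99 ± 0.67 (SE) for Pdgfrl and -1.98 ± 0.45 (SE) for Pmepa1. On the other side stood Adgre4, an adhesion receptor of myeloid cells, with a difference of 2.96 ± 0.81 (SE), and Pik3ap1, a PI3K adaptor of haematopoietic cells, with 2.29 ± 0.63 (SE). None of these genes passed the test. limma called 0 of 18193 genes at an adjusted p under 0.05, with a smallest adjusted p of 0.752.

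Galc, the lysosomal galactosylceramidase, differed by 2.22 ± 0.57 (SE), and Fam117a by 2.17 ± 0.53 (SE). The other genes named on the higher side were Sh3bp5, Rmnd5a, the sphingosine 1-phosphate receptor S1pr3, the Rac exchange factor Tiam1, the transducin-like corepressor Tle4, Foxn2, the circadian repressor Cry1 and the endothelin receptor Ednrb, with log2 differences from 1.96 down to 1.03. On the lower side were also the developmental regulator Eya1 with -1.99 ± 0.50 (SE), the receptor adaptor Grb14 with -1.81 ± 0.44 (SE) and the receptor phosphatase Ptprf with -1.60 ± 0.40 (SE). The remaining lower genes, Pcdhb16, the chromatin remodelling subunit Smarcd3, Gm20045, the actin regulator Nckap1, the fatty acid elongase Elovl4 and Gm4274, lay between -1.57 and -1.02. In each direction these were the 12 genes with the smallest unadjusted p by limma among genes with an absolute log2 difference of at least 1. None of the 24 passed. The Pten-het and Pten-WT values did not overlap for 5 of the 12 higher and 8 of the 12 lower genes. Adgre4 and Pik3ap1 were highest, at 10.40 and 11.69, in Pten-het replicate 2, the tumour with the highest neutrophil marker score of 4.92. The Galc difference came from 1 of its 3 probe sets, and the probe sets of Tle4 and Foxn2 did not all point the same way. The weakest probe set was also near 0 for Pik3ap1 (0.05), Tiam1 (0.04), Eya1 (-0.01), Grb14 (-0.06) and Pcdhb16 (-0.13). By contrast, all probe sets of Rmnd5a (1.39 to 1.73) and Pmepa1 (-2.13 to -1.42) lay well away from 0.

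At an unadjusted p under 0.05, limma found 764 genes, 336 higher and 428 lower in Pten-het tumours, against 910 expected by chance. Testing every probe set by itself gave 0 calls and 1754 of 45037 probe sets at an unadjusted p under 0.05. In 88 genes all Pten-het values lay above all Pten-WT values, and in 75 genes below. Together these are 0.9% of genes, where chance gives 1.59%. The median SD of a gene was 0.50 on the log2 scale among Pten-het and 0.29 among Pten-WT tumours. Without Pten-WT replicate 4, 3 genes passed limma at an adjusted p of 0.044, namely Rpl39l (-6.42), the Y-linked gene Eif2s3y (-4.63) and Galc (2.75).

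The sex-linked transcripts separated most Pten-WT tumours from the Pten-het tumours. Eif2s3y, a Y-linked translation factor gene, lay between 3.57 and 3.91 in the 4 Pten-het tumours and at 3.75 in Pten-WT replicate 4, but between 7.30 and 9.61 in the other Pten-WT tumours. Xist, the noncoding RNA of the inactive X chromosome, lay between 11.51 and 13.45 in the Pten-het tumours. It was at 12.90 in Pten-WT replicate 4 and 12.98 in replicate 5, and between 5.69 and 5.94 in replicates 1 to 3, so replicate 5 carried both Xist and Y-linked transcripts. Uty and Kdm5d, also Y-linked, had differences of -1.87 ± 0.64 (SE) and -1.09 ± 0.39 (SE). Adjusted over the list alone, 4 of 4 measured sex-linked genes passed limma, and over all genes none did. Rpl39l lay between 13.23 and 13.88 in Pten-WT replicates 1, 2, 3 and 5, and at 8.94 in replicate 4, inside the Pten-het range of 5.88 to 9.28. Galc showed the opposite order, with 4.46 to 4.81 in those 4 tumours, 7.34 in Pten-WT replicate 4 and 7.03 to 8.29 in the Pten-het tumours.

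**Figure D1:**
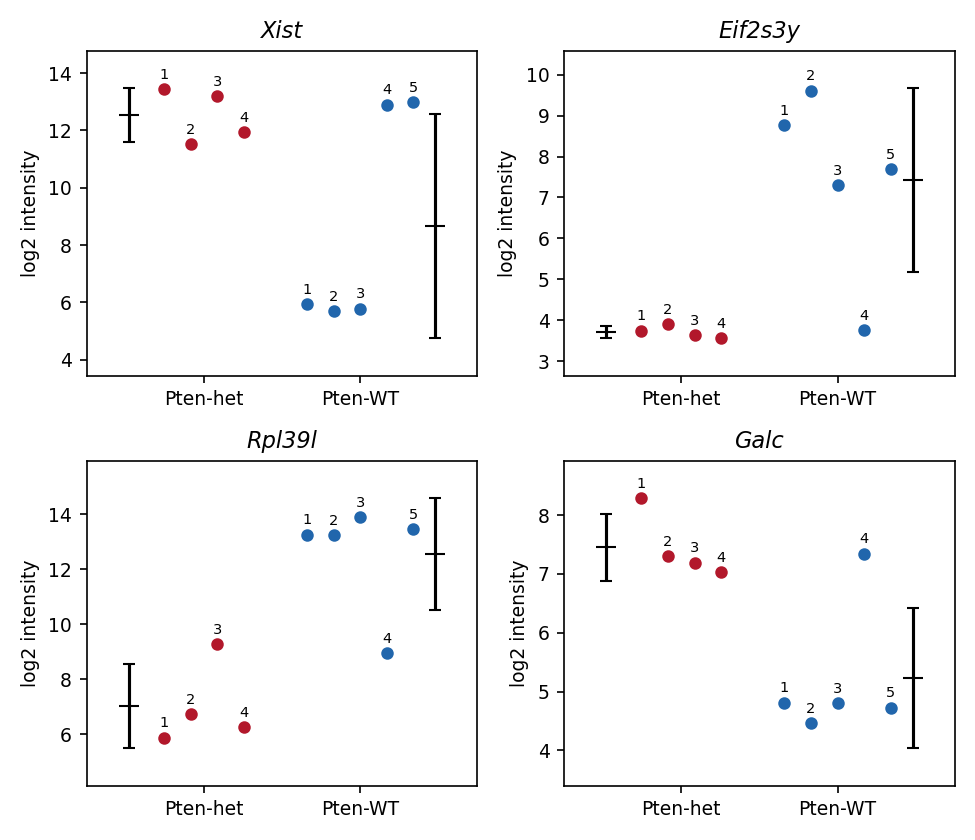
Log2 intensity (vertical axes) of Xist, Eif2s3y, Rpl39l and Galc in each tumour by genotype (horizontal axes); numbers are replicates, and black bars show the mean ± SD per genotype. Pten-WT replicate 4 lies with the Pten-het tumours for Eif2s3y (3.75) and Galc (7.34), and Pten-WT replicate 5 has high Xist (12.98) beside an Eif2s3y value of 7.70.

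None of the Notch lists passed camera in the main comparison of the genotypes. Of the 15 measured Notch target genes, 8 were higher and 7 lower in Pten-het tumours, and the mean log2 difference was 0.08. The median was 0.25, and Ccnd1 and Myc had the lowest differences. Hey1, Hey2 and Heyl, transcriptional repressors induced by Notch, had differences of 0.36 ± 0.53, 0.69 ± 0.47 and 0.58 ± 0.32 (SE), while Hes1, a widely expressed target of the same family, had -0.10 ± 0.41 (SE). The Hey2 difference came from Pten-het replicate 4, at 6.53 against 3.79 to 4.59 in the other Pten-het tumours. Ccnd1, the cyclin of early G1 phase, had the target list's smallest unadjusted p of 0.0127 by limma, with a difference of -1.77 ± 0.58 (SE), and did not pass. An exact two-sided permutation test of the mean over the list's targets per tumour over all splits of the 9 arrays gave p = 0.643, and camera gave an adjusted p of 0.506. With an estimated correlation the adjusted p was 0.646. The mean was -0.23 over the targets above the median expression of all genes and -0.04 without Pten-het replicate 4.

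Among the other targets, the ubiquitin ligase genes Dtx1 and Dtx4 differed by 1.11 ± 0.55 and 0.39 ± 0.40 (SE), Myc by -0.88 ± 0.56 (SE), and Hes7 by 0.43 ± 0.25 (SE). Dtx1 was highest, at 8.75, in Pten-het replicate 1, whose lymphoid marker scores were the highest of the 9 arrays. Hes5, Nrarp, Ptcra, Il2ra and Gata3 had differences between -0.14 and 0.25. Of the 10 receptors and ligands, 6 were higher and 4 lower, with a mean of 0.10 and a camera adjusted p of 0.629. The receptors Notch1 and Notch3 had differences of 0.58 ± 0.33 and 0.44 ± 0.46 (SE), Notch4 0.29 ± 0.61 (SE) and Notch2 -0.20 ± 0.30 (SE). The ligands Dll4, Dll1, Jag2, Jag1 and Dll3 lay between -0.05 and 0.32, and Dlk1 at -0.54 ± 0.72 (SE). The sign for Dlk1 rests on Pten-WT replicate 1, at 9.15 against 5.36 to 6.05 in all other tumours. These tallies rest on 1 probe set per gene: other probe sets had the opposite sign for Notch2 (0.14), Jag1 (up to 0.29), Hes5 (0.15), Nrarp (0.15) and Il2ra (0.31). For the remaining receptors, ligands and targets with several probe sets, all had the same sign. Those not used gave 0.62 for Notch1, 0.54 for Notch3 and 0.16 and 0.87 for Notch4. Without Pten-het replicates 1 and 2 and Pten-WT replicates 1 and 5, an alternative chosen after seeing the data, the receptors and ligands had a mean of 0.53 and a camera adjusted p of 0.0157, and with array weights 0.39 and 0.048. Of 18 measured genes of the Notch machinery, 12 were higher and 6 lower, with a mean of 0.12 and a camera adjusted p of 0.437. They include the ubiquitin ligase Itch with 0.71 ± 0.29 (SE), the presenilin Psen2 with 1.01 ± 0.52 (SE) and the DNA-binding effector Rbpj with -0.44 ± 0.35 (SE). Psen2 was highest in Pten-het replicate 1, at 9.80 against 6.96 to 8.49 in the other Pten-het tumours. Adjusted over the list alone, 0 members of any Notch list passed limma.

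**Figure D2:**
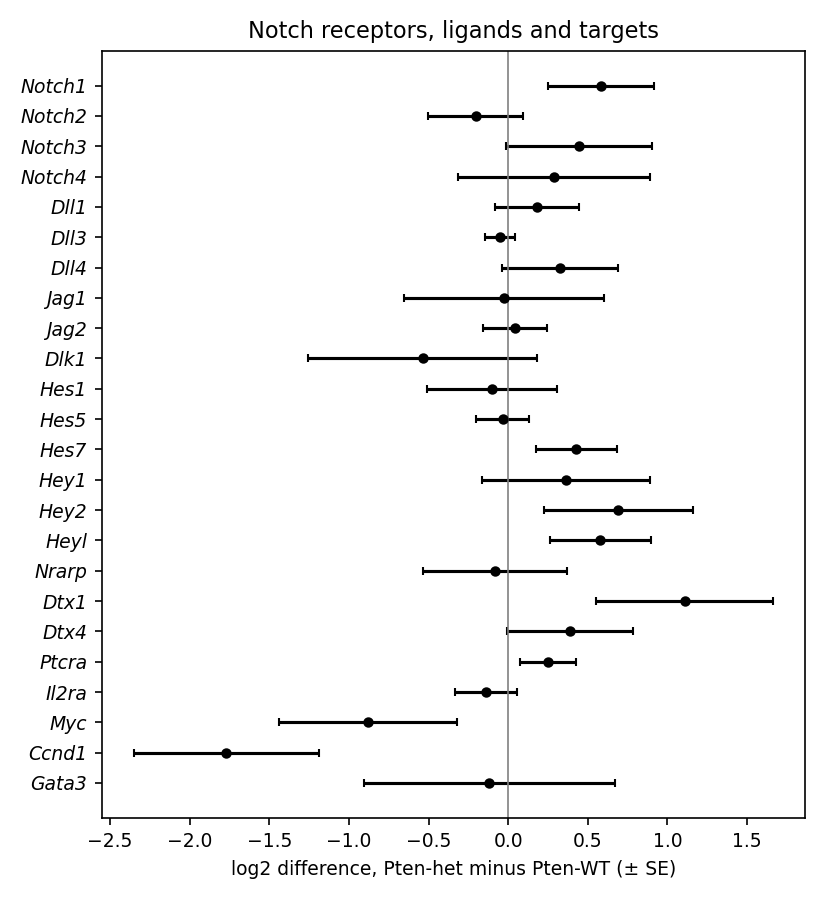
Log2 difference between Pten-het (4 tumours) and Pten-WT (5 tumours) for Notch receptors, ligands and targets (vertical axis); points are limma estimates and bars their SE. Values run from -1.77 for Ccnd1 to 1.11 for Dtx1, and no gene passed limma.

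Cell cycle genes fell as a group in the Pten-het tumours. All 24 measured proliferation genes had lower means, with a mean log2 difference of -0.90, a camera adjusted p of 3.24e-10 and an adjusted p of 0.639 with an estimated correlation. The examples with the smallest p were the survivin gene Birc5 with -1.73 ± 0.61 (SE), the centromeric histone gene Cenpa with -1.51 ± 0.55 (SE), the mitotic activator Cdc20 with -1.12 ± 0.42 (SE) and the topoisomerase gene Top2a with -1.40 ± 0.53 (SE). No single member passed limma, also when adjusted over the list alone. The list score was -1.45 and -0.95 in Pten-het replicates 1 and 2, -0.42 in replicate 3 and 0.82 in replicate 4, against 0.22 to 0.58 in Pten-WT tumours. Without Pten-het replicates 1 and 2 the mean was -0.21 with a camera adjusted p of 0.043, and without Pten-WT replicates 1 and 5 as well it was -0.18 with a camera adjusted p of 0.112. Pten-het replicates 1 and 2 also had the lowest collagen scores. Lymphoid marker scores were highest in replicate 1, and the neutrophil score was highest in replicate 2 (4.92, against -0.55 in replicate 1).

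Matrix and mesenchymal genes also fell as groups by camera, with Pten-het replicates 1 and 2 lowest. Of 19 fibrillar collagen and matrix genes 17 were lower, with a mean of -0.78 and a camera adjusted p of 0.00607 (adjusted p = 0.639 with an estimated correlation). Col3a1 and Col5a2, fibrillar collagen chains, had differences of -0.99 ± 0.65 and -1.65 ± 0.90 (SE). The 17 mesenchymal genes had a mean of -0.67 with a camera adjusted p of 0.0184 (adjusted p = 0.639 with an estimated correlation), among them the transcription factors Zeb1 with -1.25 ± 0.42 (SE) and Prrx1 with -1.96 ± 0.98 (SE) and the matrix glycoprotein Tnc with -2.16 ± 0.96 (SE). Of 15 TGF-beta response genes 12 were lower, with a mean of -0.50 and a camera adjusted p of 0.0291 (adjusted p = 0.639 with an estimated correlation). Pmepa1 was the only one to pass limma when adjusted over the list alone. The collagen score was -1.58 and -1.52 in Pten-het replicates 1 and 2 and 0.63 and 0.73 in replicates 3 and 4, and without the first pair the list mean was 0.33 for collagen and 0.16 for the mesenchymal genes. The collagen call was lost without Pten-het replicate 1 (-0.40), Pten-het replicate 2 (-0.42) or Pten-WT replicate 5 (-0.51), and the mesenchymal call without Pten-het replicate 1 (-0.29) or Pten-WT replicate 5 (-0.59). The TGF-beta call was lost without Pten-het replicates 1 (-0.44), 2 (-0.35) or 3 (-0.56) or Pten-WT replicates 1 (-0.43) or 4 (-0.37), each left out by itself.

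Interferon response genes fell as a group, 16 of 17 being lower, with a mean of -0.67 and a camera adjusted p of 0.00136 (adjusted p = 0.639 with an estimated correlation). The examples were the antiviral genes Oasl2, Mx1 and Ifit2 with -1.12 ± 0.50, -1.44 ± 0.68 and -0.91 ± 0.43 (SE) and the chemokine gene Cxcl10 with -1.39 ± 0.67 (SE). The score was lowest, at -1.22, in Pten-het replicate 4, and the call was lost without that tumour, at -0.38. Oxidative phosphorylation genes fell by a mean of 0.26 (16 of 19 lower, camera adjusted p of 0.0219, adjusted p = 0.661 with an estimated correlation), and ribosomal protein genes fell by a mean of 0.26 (12 of 13 lower, camera adjusted p of 0.024, adjusted p = 0.646 with an estimated correlation). Ndufb8 and Ndufa4, subunits of respiratory chain complexes, had differences of -0.76 ± 0.39 and -0.85 ± 0.44 (SE), and Rps6, of the small ribosomal subunit, had -0.82 ± 0.42 (SE). Without Pten-het replicate 2, both means were -0.03 and neither list passed. The respiratory list was also lost without Pten-het replicate 1 (-0.20), Pten-WT replicate 4 (-0.25) or Pten-WT replicate 5 (-0.24), and the ribosomal list without Pten-WT replicate 4 (-0.24).

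Markers of blood cells rose as groups in the Pten-het tumours, each through 1 or 2 of the 4 tumours. All 12 measured B and plasma cell markers were higher, with a mean of 0.81 and a camera adjusted p of 0.00145 (adjusted p = 0.639 with an estimated correlation). The list score was 2.38 in Pten-het replicate 1 and 0.90 in replicate 2, against -1.14 to 0.19 in Pten-WT tumours. The B cell surface gene Ms4a1 and the plasma cell gene Mzb1 had differences of 1.88 ± 0.96 and 1.73 ± 0.91 (SE). All 11 neutrophil markers were higher, with a mean of 1.69 and a camera adjusted p of 0.00219, and all 5 erythroid markers, with a mean of 1.23 and a camera adjusted p of 0.0304. For both lists the adjusted p was 0.639 with an estimated correlation. In Pten-het replicate 2 the granule protein genes Camp, Ngp and Ltf stood at 13.81, 14.35 and 13.67, and the erythroid genes Alas2 and Slc4a1 at 13.48 and 12.68. The highest values of these genes in any other tumour were 7.77, 8.02, 5.58, 6.71 and 5.27. Without Pten-het replicate 1 the B cell mean was 0.17, and without replicate 2 the neutrophil and erythroid means were 0.37 and 0.23, none of them passing. The erythroid call was also lost without Pten-WT replicate 1 (1.20), 4 (1.29) or 5 (1.24).

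FOXO targets, genes that PI3K signalling restrains through FOXO factors, rose as a group, 15 of 19 being higher, with a mean of 0.44 and a camera adjusted p of 0.0304 (adjusted p = 0.639 with an estimated correlation). Klf2, a lymphocyte and endothelial transcription factor, the proapoptotic gene Bcl2l11 and the cell cycle inhibitor Cdkn1b had differences of 1.41 ± 0.70, 1.18 ± 0.59 and 0.71 ± 0.43 (SE). Klf2 and Bcl2l11 were high only in Pten-het replicates 1 and 2 (10.32 and 10.85 for Klf2). Of these tumours, replicate 1 had the highest lymphoid scores and replicate 2 the highest neutrophil score. The FOXO call was lost without Pten-het replicate 1 (0.12) or 2 (0.38) or Pten-WT replicate 1 (0.42) or 4 (0.42), and without both of those Pten-het tumours the mean was -0.13. Immediate early genes rose by a mean of 0.50 (15 of 18 higher, camera adjusted p of 0.0189, adjusted p = 0.639 with an estimated correlation), with Fos at 1.25 ± 0.56 (SE) and Dusp1 at 1.39 ± 0.75 (SE). That call was lost without Pten-het replicate 2 (0.09) or Pten-WT replicate 1 (0.46) or 5 (0.43). Mast cell markers rose by a mean of 0.44 (9 of 10 higher, camera adjusted p of 0.0304, adjusted p = 0.639 with an estimated correlation), with the protease gene Cpa3 at 0.92 ± 0.41 (SE). The mast cell call was lost without any of Pten-het replicates 2 (0.22), 3 (0.51) and 4 (0.44) or Pten-WT replicates 1 (0.40), 4 (0.43) and 5 (0.40).

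Skeletal muscle genes were lower in the Pten-het tumours because of their levels in only 2 Pten-WT tumours. All 18 muscle markers had lower means in Pten-het tumours, and the list fell by a mean of 1.34 with a camera adjusted p of 0.00145 and an adjusted p of 0.661 with an estimated correlation. The score was 4.47 in Pten-WT replicate 1 and 2.66 in replicate 5, against -1.48 to -1.32 in the other Pten-WT tumours, -1.44 to -1.05 in Pten-het replicates 1 to 3 and 0.63 in Pten-het replicate 4. Acta1, the skeletal muscle actin gene, stood at 13.49 and 11.62 in those Pten-WT tumours, and Ckm, the muscle creatine kinase gene, at 11.81 and 9.17. The call was lost without Pten-WT replicate 1 (-0.38) or replicate 5 (-0.83), and without both of them the list mean was 0.64, with a camera adjusted p of 0.00133. The 15 myogenic progenitor markers had a mean of -0.25 and a camera adjusted p of 0.507. The sex-linked list, in which the 3 Y-linked genes were lower and Xist higher, had a mean of -0.70, a camera adjusted p of 0.024 and an adjusted p of 0.639 with an estimated correlation. It was lost without Pten-het replicate 3 (-0.75) or 4 (-0.63) or Pten-WT replicate 5 (-0.48).

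**Figure D3:**
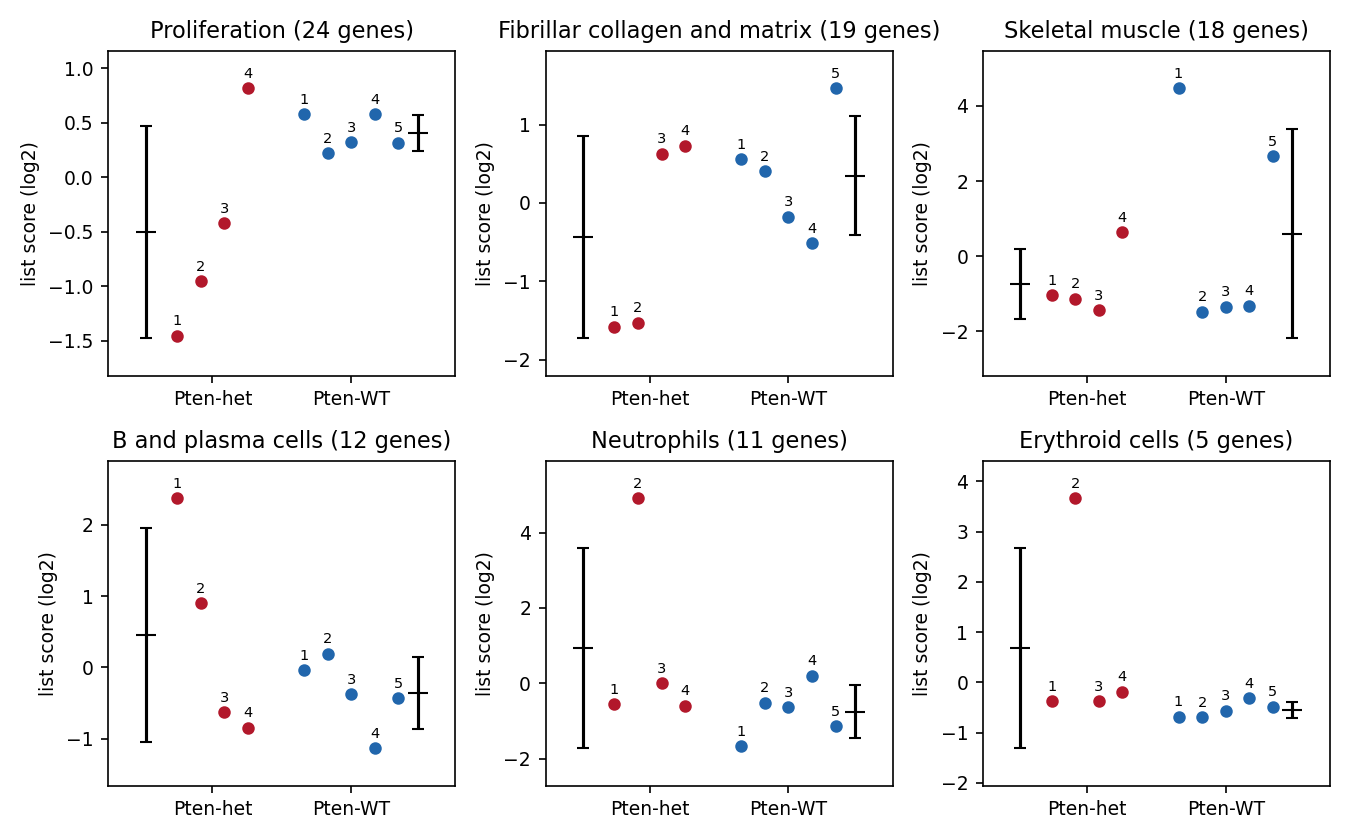
Mean log2 value of a list's genes, each centred on its mean over the 9 tumours (vertical axes), for 6 gene lists in each tumour by genotype (horizontal axes); numbers are replicates, and black bars show the mean ± SD per genotype. Pten-het replicate 1 is highest for B and plasma cell markers (2.38), Pten-het replicate 2 for neutrophil (4.92) and erythroid markers (3.67), and Pten-WT replicate 1 for skeletal muscle markers (4.47).

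The other lists did not pass camera with all 9 tumours. Among lists tied to the altered genes, the means were 0.02 for PI3K and AKT components (adjusted p of 0.805), 0.22 for mTORC1 and glycolysis genes (0.534), 0.16 for p53 targets (0.531) and -0.37 for INK4 and senescence genes (0.25), while FOXO targets passed, as given above. Single members were further apart, such as the p53 target and cell cycle inhibitor Cdkn1a with 1.20 ± 0.58 (SE), the kinase gene Pdpk1 with 0.67 ± 0.28 (SE) and the INK4 locus genes Cdkn2a and Cdkn2b with -1.81 ± 0.84 and -1.69 ± 0.77 (SE). Without Pten-het replicate 2, Cdkn1a differed by 0.54 and Cdkn2a by -1.08. Both INK4 genes were low only in Pten-het replicates 1 and 2, with Cdkn2a at 8.84 and 8.07 and Cdkn2b at 6.31 and 6.26. In Pten-het replicates 3 and 4, Cdkn2a stood at 11.98 and 12.14 and Cdkn2b at 9.95 and 8.96. The Pten-WT means were 12.07 for Cdkn2a and 9.56 for Cdkn2b. Cholesterol synthesis genes had a mean of -0.28 (camera adjusted p of 0.304) and hypoxia genes 0.11 (0.708), with the stress gene Ddit4 at 1.49 ± 0.59 (SE). Among signalling lists, hedgehog genes had a mean of -0.42 (camera adjusted p of 0.0977), with the pathway's membrane transducer gene Smo at -1.89 ± 0.71 (SE). Growth factors and receptors had -0.42 (camera adjusted p of 0.0977), with Fgfr1 at -1.85 ± 0.60 (SE) and Pdgfa at -1.50 ± 0.48 (SE), and Wnt response genes -0.27 (0.629). Matrix protease genes had a mean of -0.27 (camera adjusted p of 0.319), with Adam12 at -1.68 ± 0.68 (SE). The mean of the protease list ran from -0.54 to 0.24 with 1 tumour left out, and was 0.45 without Pten-het replicates 1 and 2.

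Of the remaining cell type lists, T and NK cell markers had a mean of 0.25 (camera adjusted p of 0.307), and antigen presentation genes had -0.04 (0.807), which turned to 0.02 under quantile normalization. Macrophage markers had a mean of 0.08 (camera adjusted p of 0.805), with the scavenger receptor Marco at 2.84 ± 0.91 (SE) and Aif1 at -1.32 ± 0.45 (SE). The means were 0.06 for endothelial (camera adjusted p of 0.773), -0.30 for pericyte and smooth muscle (0.258), 0.25 for adipocyte (0.25), -0.12 for cartilage and bone (0.971), -0.25 for epithelial (0.682) and 0.25 for Schwann cell and neural markers (0.392). Acan, the cartilage proteoglycan gene, had a difference of -1.45 ± 0.39 (SE), and the keratin gene Krt18 -2.41 ± 1.04 (SE). The median or the camera direction had the opposite sign to the mean for the PI3K, hypoxia, macrophage, cartilage and epithelial lists. Several of these lists passed camera when tumours were left out or weighted. With 1 tumour left out, they were mTORC1 (0.54), hypoxia (0.59) and antigen presentation (-0.53) without Pten-het replicate 1, cholesterol (-0.72) and T and NK markers (0.59) without Pten-het replicate 4, adipocyte markers (0.44) without Pten-WT replicate 2, and hedgehog without Pten-het replicate 2 (-0.36) or Pten-WT replicate 3 (-0.47). With another single tumour left out, 4 of these lists had means of the opposite sign and no call. The extremes were -0.21 (mTORC1), -0.22 (hypoxia), 0.41 (antigen presentation) and -0.23 (T and NK markers). Without both Pten-het replicates 1 and 2, antigen presentation (-0.92), hypoxia (0.64), cholesterol (0.45) and T and NK markers (-0.64) passed, so the calls of cholesterol and of T and NK markers ran in opposite directions depending on the tumours left out. Array weights gave calls for hedgehog (-0.28), antigen presentation (-0.39) and endothelial genes (0.36). Without Pten-het replicates 1 and 2 and Pten-WT replicates 1 and 5, antigen presentation (-0.58), T and NK markers (-0.51) and endothelial genes (0.37) passed.

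In all, 15 of the 38 lists passed camera with its preset correlation, 6 higher and 9 lower, and 0 passed with an estimated correlation, fry or the adjusted exact permutation test of list means, while 13 passed camera on ranks. By that exact test 2 lists, the erythroid markers and the hedgehog genes, had an unadjusted p of 0.0238, and the smallest adjusted p was 0.452. Other splits of the same arrays into 4 and 5 gave a median of 10 lists passing camera with the preset correlation. The count was 7 without Pten-het replicate 2, 9 without Pten-WT replicate 1, 9 without Pten-WT replicate 4 and 7 without Pten-WT replicate 5. Without Pten-het replicates 1 and 2 it was 6, of which 2, proliferation (-0.21) and interferon response (-0.74), were shared with the 15 in the same direction. Adjusted over the list alone, members passed limma in the sex-linked and TGF-beta lists and in none of the other 36.

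Pten-het replicates 1 and 2 stood apart from the other 7 tumours over the whole profile. The first principal component held 42.1% of the variance and placed them at -88.1 and -118, with the other tumours between 19.9 and 38.6. They also differed from each other, with a Pearson correlation over genes of 0.857, while pairs among the other 7 tumours had 0.937 to 0.976. Pairs within a genotype had a mean correlation of 0.920 and pairs across genotypes 0.904. This difference of 0.0161 was within the spread between tumours, with a one-sided exact permutation p of 0.151 over all splits. Without Pten-het replicates 1 and 2 it was -0.00153 with an exact p of 0.571.

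**Figure D4:**
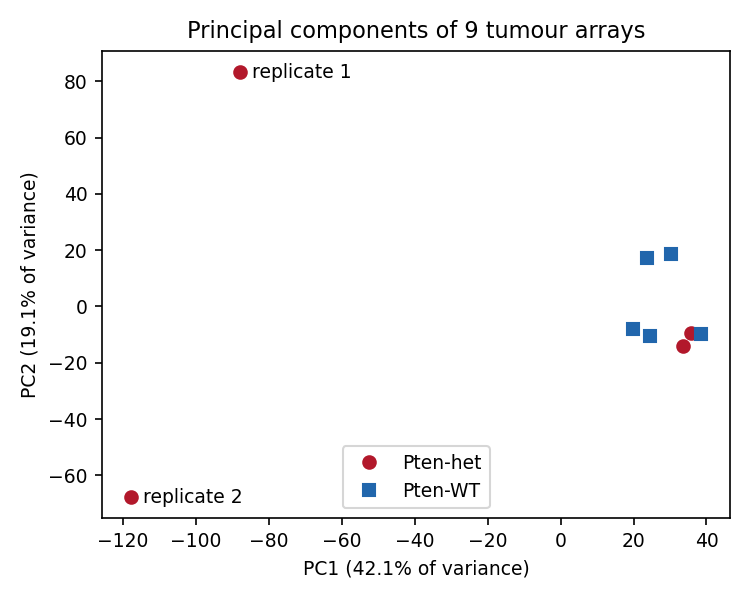
Scores of the 9 tumours on the first (horizontal axis, 42.1% of the variance) and second (vertical axis, 19.1%) principal components of 18193 genes; circles are Pten-het and squares Pten-WT tumours. Pten-het replicates 1 and 2 lie at -88.1 and -118 on the first component, and the other 7 tumours between 19.9 and 38.6.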

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

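All tests of explanations in this part were chosen after the results were seen. In 172 groups of 4 or 5 tumours, 1 tumour lay far from the rest of its genotype 15 times, where chance gives about 1 in 20 groups, or 8.6. Pten-het replicate 2 accounted for 4 of these, Pten-WT replicate 4 for 4 and Pten-WT replicate 1 for 3.

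Pten-het replicate 2 was far above its group in the scores of neutrophil (4.92), erythroid (3.67) and immediate early genes (1.52) and below it for ribosomal proteins (-0.82), and together with Pten-het replicate 1 it stood apart from the other 7 tumours. A genotype effect common to all 4 Pten-het tumours stays open, because no pairing of these tumours could test it. Replicates 1 and 2 and replicates 3 and 4, as differences from disjoint sets of Pten-WT arrays, correlated at a median of -0.129 over genes. Replicates 1 and 2 were paired because they stood apart, so this value does not decide. The other pairings gave medians of 0.235 and 0.251. Each of them set replicate 1 against replicate 2, so the shift these share from the other 7 tumours could by itself give a positive value. RNA degradation stays open in both replicate 1 and replicate 2. In replicate 2 the 3' to 5' log2 ratios of Actb and Gapdh lay on average -0.80 from the highest of the other 7 arrays, both below it. The Actb ratio of replicate 2, 0.17, was the lowest of the 9 arrays. Its Gapdh ratio, 0.64, lay inside the range of the other 7 (0.20 to 0.95), so the ratios do not decide. In replicate 1 (-0.0928) only the Gapdh ratio lay above. Blood or marrow cells in replicate 2 and lymphoid cells in replicate 1 stay open: 16 of 16 neutrophil and erythroid markers were highest in replicate 2, and 22 of 29 B, plasma, T and NK markers in replicate 1, but the scores of the same lists raised this explanation, so the counts restate it. No test separated sampled tissue from infiltrating cells.

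Pten-WT replicate 4 was far from its group for Galc (7.34 against 4.46 to 4.81) and Rpl39l (8.94 against 13.23 to 13.88), both times on the Pten-het side, as it was for the Y-linked genes. Galc in this tumour lay 2.64 above the mean of the other Pten-WT tumours, which restates the observation, so genotype stays open as an explanation for as long as a wrong label on this tumour does. The sex of the animals stays open: 3 genes, Galc, Rpl39l and Eif2s3y (which defined the signal), were at least 2 log2 units apart between tumours with and without Y-linked signal, but Xist did not part the same tumours because Pten-WT replicate 5 had both. A wrong genotype label on Pten-WT replicate 4 stays open, since its mean correlation with Pten-het minus that with the other Pten-WT arrays, -0.0451, was the highest of the 5 Pten-WT arrays by only a fraction of their spread. None of these can be told apart from a difference in strain background or colony, which was not tested, because no label gives sex, litter or the origin of the alleles.

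Skeletal muscle genes were high in Pten-WT replicates 1 and 5, with median excesses of 5.80 and 3.93 over the other 7 tumours. Muscle fibres in these samples may account for this, since the muscle markers exceeded the myogenic progenitor markers by 3.32 or more in both. A myogenic programme in the tumour cells stays open, because the progenitor markers had a median excess of 0.52 or more, with Myh3 and Myh8 raised but Myod1 at 5.00 and 4.67 and Myog at 4.39 and 5.08, near the level of the other tumours. No biological explanation from the design was tested for this pattern.

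The remaining tumours far from their groups are given as values. Pten-WT replicate 1 was low for the hypoxia score (-1.34) and high for Dlk1 (9.15) and Il2ra (5.42), and Pten-WT replicate 3 was low for the hedgehog score (-0.01) and high for Hes5 (6.36). Pten-WT replicate 4 was high for Gata3 (7.88) and low for Hey2 (3.94), and Pten-het replicate 1 was high for Gata3 (6.60). Pten-het replicate 4 was high for S1pr3 (10.91).

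Over 100 drawn splits of the 9 arrays into 4 and 5, chance was not excluded for the count of lists or of genes at an unadjusted p under 0.05. For limma at an adjusted p under 0.05 the real split gave 0 genes, which all 100 splits must equal or exceed, so the comparison says nothing about chance. The highest other split gave 3 genes and set Pten-WT replicates 1, 2, 3 and 5, the tumours with Y-linked signal, against the rest. At an unadjusted p under 0.05 the real split gave 764 genes, 34 of the 100 splits gave as many, and the highest other gave 3556. That split joined Pten-het replicates 1 and 2 with Pten-WT replicates 1 and 5. It was picked for its count, and whether it reflects a structure of the samples other than genotype was not tested. For lists passing camera the real count was 15, 10 of the 100 splits gave as many, and the highest other gave 17. The other splits had a median of 10 passing lists, and 99 of them had at least 1. A camera call with the preset correlation is therefore by itself no evidence of a genotype effect.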

How the results depend on the processing

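Leaving out arrays in pairs or 4 at once and the Y-linked covariate were chosen after seeing the data. The count of genes stayed at 0 under block, scaling, weights, variance prior, filter, probe set and looser adjusted thresholds, and was 48 at an unadjusted p under 0.01 with a log2 difference of at least 1, and 0 to 3 with 1 array left out. The Y-linked covariate (11 genes) compares the Pten-het tumours with Pten-WT replicate 4 alone, as all arrays with that signal are Pten-WT; the lone tumour is assumed to vary like the others, so its values are not estimates for the genotype. The 15 lists became 9 with the replicate block, which also drops Pten-WT replicate 5 because it has no partner (7 lists without that tumour alone), 8 with array weights, 4 among genes above the median (fewer genes tested), 6 without Pten-het replicates 1 and 2, 7 without Pten-WT replicates 1 and 5, 7 without all 4, 9 with the Y-linked covariate, 0 with estimated correlation, fry or exact permutation, and 7 to 16 with 1 array left out. Quantile normalization gave 4 higher and 7 lower lists against 6 and 9. Whether replicate numbers pair the samples was not settled, because no chance level was computed for the check. The correlations of deviations were 0.14, 0.08, 0.32 and -0.15, with 2 of the 4 best with their own number. Since the block also drops a tumour, its count of 9 is not an effect of pairing alone. The Notch target mean was -0.23 among genes above the median, -0.26 with the Y-linked covariate and -0.0415 to 0.16 with 1 array left out; the likeness difference was -0.00153 without Pten-het replicates 1 and 2 and 0.00312 to 0.044 with 1 array left out.

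Some lists turned direction, and apart from arrays left out the cause was not tested. Without Pten-het replicates 1 and 2, means of turned lists with a call in either fit were -0.13 (FOXO), 0.45 (cholesterol), 0.17 (oxidative phosphorylation), 0.16 (mesenchymal), 0.33 (collagen), -0.64 (T and NK) and -0.38 (B and plasma). Also without Pten-WT replicates 1 and 5 these means were -0.13, 0.26, 0.17, 0.38, 0.77, -0.51 and -0.30, with immediate early genes at -0.11. Without Pten-het replicates 1 and 2, lists with no call in either fit turned to -0.26 (adipocyte), 0.12 (INK4), 0.45 (matrix proteases), -0.06 (p53 targets), 0.05 (growth factors) and -0.07 (Notch machinery). Skeletal muscle was 0.64 without Pten-WT replicates 1 and 5, 0.98 without all 4 and 0.57 with the Y-linked covariate, which gave 0.0798, 0.0769 and 0.0785 for mesenchymal, collagen and interferon genes. Array weights gave 0.00102 (mesenchymal) and 0.15 (collagen), and the mean of all probe sets 0.19 for sex-linked genes. Of these turned lists, cholesterol and T and NK without Pten-het replicates 1 and 2, T and NK and collagen without all 4, skeletal muscle in both sets left out, and sex-linked genes passed camera. No named gene passed in the main fit, so none had a call to keep. Named genes kept their direction without a call in 3941 of their alternatives, passed in 3 and changed direction, with no call in either fit, in 170. Lists kept their direction and stayed with or without a call in 700, lost the call in 147 and gained it in 18. They changed direction in 23 with a call in either fit and in 56 with none. Pten and Trp53 levels and their alternatives were not run. Genes near the floor of intensity, such as Dll3 and Hey2, limit what can be seen.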

Other observations

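Tests in this part were all chosen after the results were seen. Some genes, chosen after their values were seen, were high in single tumours. Pten-het replicate 1 had the immunoglobulin genes Ighm and Jchain at 13.78 and 14.05, the T cell receptor subunit gene Cd3d at 11.82, the lymphocyte homing receptor gene Ccr7 at 10.33 and Glycam1, a mucin of lymph node venules, at 10.47. The highest values in any other tumour were 11.33, 9.95, 8.68, 6.75 and 5.38. Pten-het replicate 2 had, beside its granulocyte and erythroid genes, the platelet genes Ppbp at 13.62, Tubb1 at 12.47 and Gp9 at 11.70, against at most 6.23, 4.74 and 5.98 elsewhere.

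Some epithelial genes, chosen after their values were seen, were high in Pten-WT replicate 4. The score of the epithelial list was highest there, at 0.75, with 5 of its 18 genes highest in this tumour, but Dsp was at 3.88, near its lowest, and Trp63 was higher in Pten-WT replicate 5 (6.67 against 6.49). The secreted protein gene Wfdc2 stood at 12.36 against at most 6.75 in the other tumours, the transcription factor gene Foxa1 at 8.03 against 5.10, the keratin gene Krt8 at 9.02 against 7.24 and the desmosomal gene Pkp1 at 8.43 against 5.22. Krt18 was at 10.66 there and higher, at 11.81, in Pten-WT replicate 2. The granzyme genes Gzmd, Gzme, Gzmf and Gzmg also had their highest values in Pten-WT replicate 4, at 8.95, 8.83, 8.76 and 7.91.

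Neighbouring genes were high together in single tumours. Over 9081 expressed genes in RefSeq order, windows of 7 genes were compared with the 95th percentile of the highest window in 200 shuffled orders, and 21 runs lay above it and 12 below the matching lower bound. In Pten-WT replicate 2 a run with the Hippo effector gene Yap1 (14.05 against a median of 9.58 in the other 8 tumours), the apoptosis inhibitor genes Birc2 (13.59 against 9.06) and Birc3 (13.33 against 9.78), Dcun1d5, Tmem123, Cfap300 and several matrix metalloproteinase genes had a best window of 4.46, against a bound of 1.18. In Pten-het replicate 3 the neighbouring Mmp13, Mmp3 and Mmp10 were also high (12.47, 12.81 and 11.16), but Birc2 was at 8.99 and Birc3 at 9.66.

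In Pten-WT replicate 3 a run held the receptor kinase gene Met (12.93 against 9.31), the caveolin genes Cav1 and Cav2, Tes, Capza2, St7, Lsm8 and Wasl, with a best window of 2.89 against 1.19. Met was also high in Pten-het replicate 3, at 13.03, with Cav1, Cav2, Tes and Capza2 but not Lsm8. That tumour had another run with Sem1, Sdhaf3, the asparagine synthetase gene Asns (12.58 against 9.63) and C1galt1, with a best window of 2.95 against 1.27. In Pten-WT replicate 5 a run held Jun (11.96 against 9.96), Mysm1, Fggy, Nfia (12.07 against 7.59) and Usp1, with a best window of 2.41 against 1.57.

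A hypothesis is that some of the 21 higher runs come from copy number gain in these tumours. Co-regulated families of neighbouring genes could also give such runs. Leaving out genes of a shared name root left too few genes in 9 of the 21, the run of Yap1 among them. Of the other 12, 10 stayed above their bound, but in 8 of these, such as that of Jun in Pten-WT replicate 5, the best window held no such gene, so the check moved nothing. The runs of Met in Pten-WT replicate 3 and Asns in Pten-het replicate 3 lost genes and stayed above, while 2 runs, those of Met in Pten-het replicate 3 and of the Ifit genes in Pten-WT replicate 2, did not. The explanations cannot be told apart for the runs as a set, because few runs were open to the check and DNA copy number was not analysed here.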
